A study of Mus musculus with 3 samples.

How the data were processed

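Expression was measured by RNA sequencing of polyA RNA from primary cells of mouse skeletal mesenchyme at E15.5, extracted with a Qiagen RNeasy kit and prepared with an Ion Total RNA-Seq kit. There was 1 library for each of 3 genotypes, grouped as the labels give them: control, cKO and dTF-cKO. The values are raw read counts per gene as deposited, whole numbers under a header reading Count, with no normalisation applied. The genome build was mm10 per the submitters' processing notes. The aligner, the counting tool, the annotation and the strand setting are not given in the sources used here. Each table listed 43280 genes, of which 39354 symbols matched the GENCODE vM21 annotation of GRCm38, used for coordinates. Another 27 symbols had been turned into dates before deposit; they held at most 0.180% of a library's counts, 2 of them were repeated, and none is named. Library totals ran from 2678457 to 3634819 counts, and 3 counts, the limit that a count of 0 allows, corresponded to 0.839, 1.06 and 1.07 CPM in the control, cKO and dTF-cKO.

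Counts were scaled with TMM factors in edgeR 4.0.16 under R 4.3.3; the factors were 0.984, 1.06 and 0.963. Log2 CPM used a prior count of 2. A gene was measured if its mean over the libraries was at least 5 CPM, which kept 12127 genes, 11637 of them matched to the annotation. With no replicates, neither a p-value nor a test of genotype was computed. A gene was counted as higher or lower when its log2 difference was at least 1 in size, a 2-fold difference. Folds of named genes are ratios of scaled counts without the prior count, with an exact conditional (Clopper-Pearson) 95% interval. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only and leave out the spread between embryos. Where a library had 0 counts, the fold was computed against 3 counts and is given as a lower bound, which leaves out the counting error of the other library, and list medians are also given with such genes at their bound where that changed them.

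The 3 comparisons were cKO against control, dTF-cKO against control, and dTF-cKO against cKO. Their log2 differences are the first-named library minus the second. Each of 35 gene lists was summarised by its count of higher and lower genes, its median, and the percentile of that median among 10000 random lists drawn from 10 strata of mean expression. A percentile was computed for lists of at least 5 measured genes. It sets a list against other genes of the same library pair and tests no genotype. Older symbols were matched through synonyms, which found 10 genes listed under another name; 3 symbols were not found, 1 of them a second name of Lor, which is in the tables. The summary of 1 list and the values of some genes are not reported here. The lists, the comparisons, the size rule, the floor and the named genes were fixed before the data were examined. Named genes were Ctnnb1 and Twist2. From each comparison the rule took the 12 highest and 12 lowest measured genes with a counting interval excluding 1 and a symbol that is not a predicted model. From each list it took up to 6 genes at least 2-fold different, or the 2 most abundant where fewer than 2 were. Genes outside that rule are described as chosen after their values were seen.

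The correlation of the differences from the control was set against 50 simulated sets of libraries with no genotype effect, with counting error alone and with an added dispersion of 0.16, an assumed value. The same sets gave the number of genes at least 2-fold different with no effect. The calls were tested on simulated data in which 200 genes were altered: 95% to 96% of 4-fold differences and 45% to 55% of 2-fold differences were called, and 95.8% to 96.1% of intervals covered the true ratio. Those data had counting error only and an otherwise shared expression profile. They do not show how the calls fare with spread between embryos or with large shifts in composition. Alternatives fixed in advance included scaling to library totals, DESeq2 1.42.0 median-of-ratios factors, and totals without the 20 most abundant genes of each library. The genes left out of every total were the union over the 3 libraries, called the 20 most abundant genes below. Others were prior counts of 0.5 and 10, no expression floor and a floor 4 times as high. The rest were size rules of 1.5-fold and 3-fold, counting intervals that exclude 1, and removal of gene lists of other tissues. A scaling that sets the median difference of 57 genes of the dermis, meninges, smooth muscle and pericyte, and endothelium lists to 0 was added after the data were seen. It was applied to each comparison separately, so it is not a single set of library factors. Copies with near-identical sequence, such as Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Hspa1a and Hspa1b, and ribosomal protein genes with their pseudogenes, have uncertain counts. Reads were not available, so allele-specific and exon-level counts of Ctnnb1 were not made.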

Results

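RNA was sequenced from the skeletal mesenchyme of mouse embryos at E15.5, which the series describes as calvarial, the tissue that forms the flat bones of the skull and the connective tissue around them. There was 1 library for each of 3 genotypes at Ctnnb1. This gene encodes beta-catenin, which holds cadherins at cell contacts and, with TCF/LEF factors, carries the transcriptional output of Wnt signalling. The control carried floxed alleles on both chromosomes (fx/fx) and no Cre. The library called cKO here was fx/fx with Dermo1-Cre, a recombinase expressed from the Twist2 locus in mesenchymal cells. The library called dTF-cKO was fx/dm with the same Cre. The labels do not define dm; in mouse genetics a Ctnnb1 allele of that name makes a protein that keeps its function in adhesion and lacks transcriptional output. The libraries held 3634819 counts for the control, 2678457 for the cKO and 2905264 for the dTF-cKO. Counts above 0 were found for 19574, 18757 and 18602 genes in the same order, and 12127 genes passed the expression floor. With 1 library per genotype no difference has a replicate check, so each comparison is between libraries and no test of a genotype was possible. Intervals cover counting error only.

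The 3 libraries differed in what filled them. Col1a1 and Col1a2, the chains of type I collagen, the main protein of bone matrix, took 17.6% of control counts (exact 95% interval 17.57% to 17.64%). They took 4.04% of cKO counts (4.02% to 4.07%) and 0.766% of dTF-cKO counts (0.756% to 0.776%). The 51 keratin genes, structural genes of epithelia, took 0.0156% of counts in the control, 2.15% in the cKO and 1.79% in the dTF-cKO. The 8 globin genes took 0.636%, 0.568% and 1.53%. The 10 most abundant genes held 25.5%, 16.6% and 7.15% of counts. The libraries also differed in sex-linked transcripts. Xist, the RNA that silences an X chromosome in female cells, had 1233 counts in the control, 0 in the cKO and 2 in the dTF-cKO. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 0 counts in the control, which allows up to 0.839 CPM (counts scaled to library size), and to 362 and 444 counts in the Cre-carrying libraries. Genotype and sex-linked expression therefore differed together.

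Ctnnb1, the targeted gene, was lower in both Cre-carrying libraries than in the control, except in the dTF-cKO under a scaling added after the data were seen. It stood at 1026 CPM in the control, 745 CPM in the cKO and 442 CPM in the dTF-cKO. The ratio to the control was 0.726 for the cKO (0.688 to 0.766) and 0.430 for the dTF-cKO (0.403 to 0.459). Between the Cre-carrying libraries the ratio was 0.593 (0.552 to 0.636). The log2 differences from the control were -0.46 and -1.22. The added scaling, called the stroma scaling here, sets the median difference of 57 genes of dermis, meninges, vessel wall and endothelium to 0 in each comparison separately. Values under it therefore do not add up across the 3 comparisons. The pooled median of the 57 genes is 0 by construction, while the medians of the 4 separate lists can differ from 0. Under it the differences from the control were -0.79 and 0.57, and the difference between the Cre-carrying libraries was 1.13 in place of -0.75. Counts cover the whole gene, on chromosome 9 from 120929216 to 120960507 on the plus strand of mm10, so transcripts of the floxed, recombined and dm alleles were not separated. Twist2, which encodes a bHLH factor of dermal and bone progenitors and whose locus carries the Cre, had 21, 80 and 35 counts. It was 4.82-fold higher in the cKO than in the control (2.95 to 8.20) and 2.13-fold higher in the dTF-cKO (1.21 to 3.85). Only the Cre-carrying libraries have the Cre at this locus, so a response of Twist2 cannot be told apart from the altered locus.

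**Figure D1:**
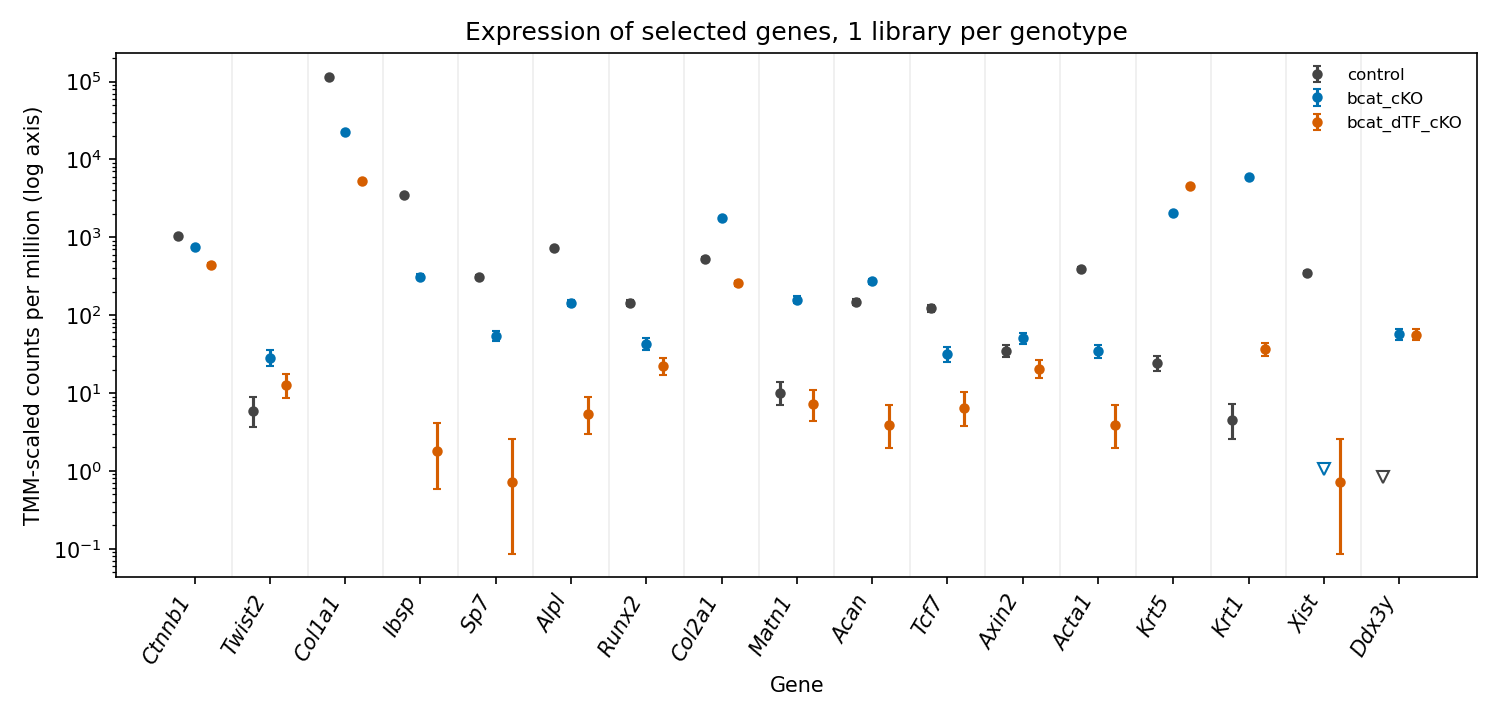
Normalised counts (CPM, log axis) of 17 genes in the 3 libraries, chosen after their values were seen: points are single libraries, bars are exact Poisson 95% intervals, and open triangles mark the CPM of 3 counts where the count was 0. Ctnnb1 runs from 1026 CPM in the control to 442 CPM in the dTF-cKO, while Ibsp runs from 12627 counts to 5.

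The first comparison asks which genes differ when beta-catenin is deleted with Dermo1-Cre. Genes of bone formation were lower in the cKO library than in the control. Of 25 measured members of the osteoblast differentiation list, 22 were at least 2-fold lower and 0 at least 2-fold higher. The median log2 difference was -2.04, below all 10000 random lists of matched expression (central 95%, -0.18 to 0.30). Ibsp, a mineral-binding protein of bone matrix, was 11.3-fold lower (10.5 to 12.1). Panx3, a channel protein of osteoblasts and late chondrocytes, was 12.1-fold lower (8.86 to 16.8). Phospho1, Smpd3 and Tnn, genes of mineralisation and bone matrix, were 6.83-fold, 6.16-fold and 8.77-fold lower. Runx2 and Sp7, the transcription factors required for osteoblast formation, were looked up after the values were seen. Runx2 was 3.35-fold lower (2.74 to 4.11) and Sp7 5.64-fold lower (4.76 to 6.73). Of 21 osteoprogenitor and suture mesenchyme genes, 6 were at least 2-fold lower and 0 higher (median -0.63, below all random lists). They included Six2 at 2.09-fold lower (1.73 to 2.53) and Gli1 at 2.08-fold lower (1.67 to 2.62).

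Cartilage genes went the other way. Of 22 chondrocyte genes, 12 were at least 2-fold higher and 1 lower, with a median of 1.06, above all random lists (central 95%, -0.20 to 0.32). Matn1, a cartilage matrix protein, was 15.7-fold higher (11.2 to 22.8), Comp 6.46-fold higher (3.87 to 11.4) and Col9a1 3.57-fold higher (3.03 to 4.22). Snorc, a cartilage proteoglycan listed under the symbol 3110079O15Rik, had 0 counts in the control and 33 in the cKO and was at least 13.9-fold higher against the floor (95% lower limit 10.7). Col2a1, the main cartilage collagen, was chosen after its value was seen and was 3.34-fold higher (3.17 to 3.52). The lower member, chosen in the same way, was Col11a2 at 2.98-fold lower (2.81 to 3.16). Genes of hypertrophic cartilage were not among the higher ones: 7 of 9 were at least 2-fold lower and 0 higher (median -2.34, below all random lists). Mmp13, a collagenase of the growth plate, was 7.82-fold lower (5.60 to 11.2) and Ihh, a hedgehog ligand, 6.44-fold lower (2.93 to 16.7). The list held 10 genes, and 6 of them also stood in other lists. Panx3, Ibsp, Alpl and Pth1r stood in the osteoblast list, so in each comparison the hypertrophic result partly repeats the osteoblast one.

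Members of the Wnt/beta-catenin target list went both ways in the cKO. Of 25, 4 were at least 2-fold higher and 3 lower, with a median of 0.20 at percentile 89.0 of the random lists. The lower ones were Tcf7, a TCF/LEF factor, at 3.89-fold (3.09 to 4.94), and the secreted Wnt antagonists Wif1 at 3.50-fold (2.87 to 4.29) and Dkk1 at 3.48-fold (2.40 to 5.18). Rnf43, which removes Wnt receptors from the membrane, was higher at 4.96-fold (2.66 to 9.94), as was Twist2, whose locus carries the Cre. Lef1 was higher at 2.12-fold (1.41 to 3.22), and Apcdd1, chosen after its value was seen, at 2.02-fold (1.71 to 2.39). Axin2, a widely used Wnt target chosen in the same way, was 1.45-fold higher (1.13 to 1.85). Of 38 Wnt ligands and receptors, 9 were higher and 4 lower (median -0.16, percentile 1.97). Wnt4 was 21.3-fold higher (13.8 to 34.4), Wnt7b 10.6-fold (7.74 to 14.8) and Fzd10 5.89-fold (4.13 to 8.60). The 4 lower ones, chosen after their values were seen, were Sfrp4, Frzb, Ror2 and Rspo1, between 2.11-fold and 3.87-fold. Of 20 beta-catenin partners, Jup and Lef1 were at least 2-fold higher and Tcf7 lower (median -0.17, percentile 2.41). Jup, which encodes plakoglobin, the nearest relative of beta-catenin, was 9.62-fold higher (8.50 to 10.9). Of 18 adherens junction genes, 3 were higher and 3 lower (median 0.22, percentile 89.9). Cdh1, the epithelial cadherin, was 5.68-fold higher (4.69 to 6.92) and Cdh2, a mesenchymal cadherin, 3.82-fold lower (3.15 to 4.67). Epidermis and hair genes, a list that includes Cdh1, were higher in the same library (median 6.65). Whether the higher counts of Jup, Wnt4, Wnt7b, Fzd10 and Cdh1 came from epidermal or mesenchymal cells was therefore not separated. The same limit holds for the higher Wnt targets Rnf43, Lef1, Apcdd1 and Axin2.

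Other cell types differed at the same time. Of 18 epidermis and hair genes, 17 were at least 2-fold higher in the cKO and 0 lower. Their median was 6.65, or 6.53 with genes at 0 set to their bound, above all random lists. The keratins of the upper epidermal layers, Krt1 and Krt10, were 1311-fold (807 to 2295) and 1183-fold higher (773 to 1911), and Lor, a protein of the cornified layer, 760-fold (435 to 1471). Other genes of the cornified layer, Dmkn, Krt77 and Hrnr, had 2, 3 and 3 counts in the control and 4960, 5648 and 4270 in the cKO. Of 5 melanocyte genes 3 were higher (median 3.17, percentile 99.96), with Dct at 38.2-fold (16.01 to 119). Only 2 of the 7 genes on that list reached the floor in the control, so other members were measured only through the Cre-carrying libraries, which favours higher values there. Of 20 skeletal muscle genes, 20 were at least 2-fold lower (median -2.31, below all random lists). Among them Myh7 was 25.2-fold lower (11.4 to 69.5) and Acta1 11.4-fold lower (9.26 to 14.1). Of 7 osteoclast genes, 5 were lower (median -1.56, below all random lists), among them Mmp9 at 9.57-fold (7.95 to 11.6). Of 16 macrophage and leukocyte genes, 6 were higher and 0 lower (median 0.73, percentile 99.98), with Pf4 at 3.37-fold (2.53 to 4.52). The endothelial list had a median of 0.45 (percentile 99.6), with Vwf at 2.49-fold higher (2.19 to 2.85). The erythroid median was -0.07 (percentile 28.6), and 0.03 when libraries were scaled to their totals. Of 11 neuron and glia genes, 5 were lower and 1 higher (median -0.71, percentile 0.15), with Fabp7 at 16.3-fold lower (9.19 to 32.1).

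Across the 12127 genes, 1172 were at least 2-fold higher in the cKO and 822 at least 2-fold lower, and the counting interval of the ratio excluded 1 for 1964 of these. Simulated libraries with no genotype effect and an assumed dispersion of 0.16 between embryos gave 1459.6 higher and 1437 lower, more than were observed, so these counts do not exceed what such a spread alone gives. The stroma scaling gave 840 higher and 1347 lower. It put the medians of the Wnt target and adherens junction lists at -0.13 and -0.11; a 4-fold higher expression floor put the Wnt target median at -0.036.

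**Figure D2:**
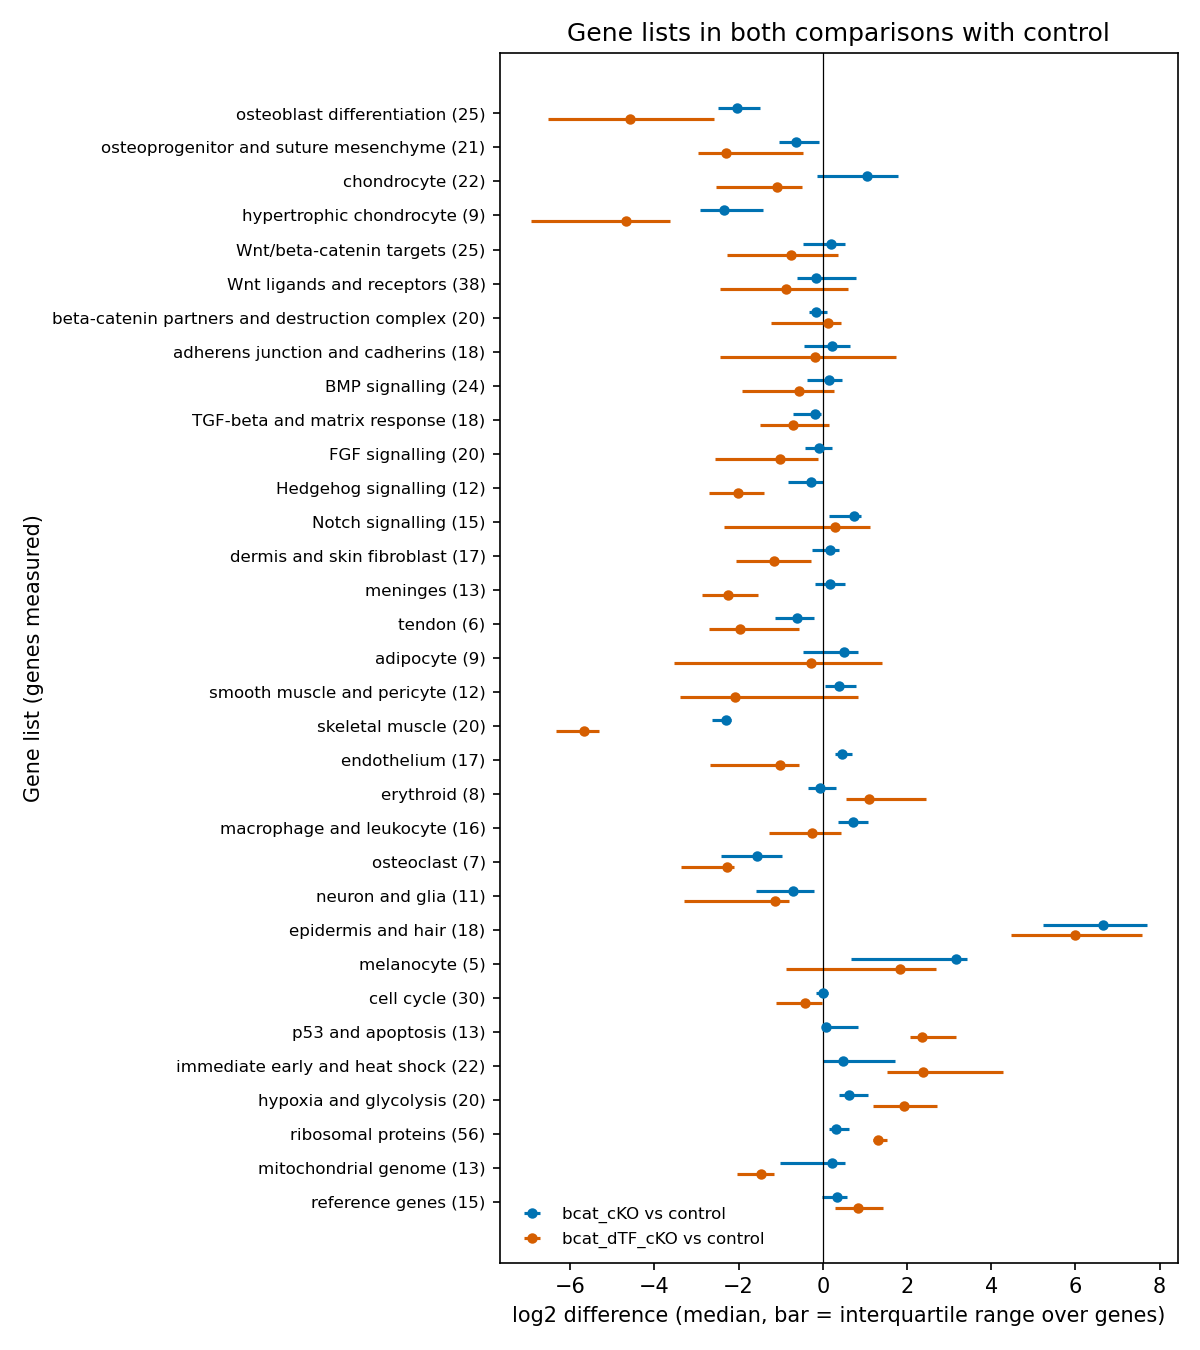
Median log2 difference from the control of the gene lists (points) with the interquartile range over genes (bars), for the cKO and the dTF-cKO, with the sex-linked and Hox lists not drawn. Osteoblast medians are -2.04 and -4.58, chondrocyte medians 1.06 and -1.08, and epidermis medians 6.65 and 5.99; under the stroma scaling, which moves every list by the same -0.33 or 1.78, 9 of 35 medians for the cKO and 14 of 35 for the dTF-cKO change sign, the chondrocyte median of the dTF-cKO among them at 0.70.

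The dTF-cKO was compared with the control to ask which genes differ when the dm allele is the one left after recombination. The control was fx/fx, and there was no fx/dm library without Cre. Carrying the dm allele and recombination of the floxed allele are therefore not separated. Genes of bone formation were lower in the dTF-cKO than in the control. Of 25 osteoblast genes, 23 were at least 2-fold lower and 1 higher. The median was -4.58, or -4.45 with genes at 0 set to their bound, below all random lists (central 95%, -0.46 to 0.63). Under the stroma scaling it was -2.80, against -2.37 in the cKO. Ibsp had 12627 counts in the control and 5 in the dTF-cKO, which was 1977-fold lower (interval from 847). Sp7 was 427-fold lower, with 2 counts in the dTF-cKO (118 to 3534). Panx3 had 0 counts and was at least 171-fold lower against 3 counts (95% lower limit 139). Alpl, the phosphatase of mineralising bone, was 136-fold lower (82.5 to 244), and Dmp1, a gene of late osteoblasts and osteocytes, 361-fold lower (99.6 to 2985). The higher member was Atf4, a stress-responsive factor chosen after its value was seen, at 2.705-fold (2.45 to 2.98). Of 21 osteoprogenitor genes, 13 were lower and 0 higher (median -2.29, below all random lists; -0.51 under the stroma scaling, against -0.96 in the cKO). Alx4, a homeobox gene of skull bone formation, was 42.8-fold lower (23.8 to 86.3), and the mesenchymal genes Msx1, Pdgfra and Prrx1 were 11.7-fold, 7.97-fold and 7.87-fold lower. Runx2, looked up after the values were seen, was 6.47-fold lower (4.96 to 8.56).

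Cartilage genes were lower too. Of 22 chondrocyte genes, 12 were at least 2-fold lower and 1, Snorc, higher (0 and 10 counts, 95% lower limit 2.86-fold); the median of -1.08 (percentile 0.01) became 0.70 under the stroma scaling. Acan, the main cartilage proteoglycan, was 37.9-fold lower (21.03 to 76.5), and Col11a2 24.5-fold lower (21.1 to 28.7). Of 9 hypertrophic genes, 7 were lower and Vegfa, chosen after its value was seen, was 5.96-fold higher (5.23 to 6.80). That median was -4.67, or -3.89 with bounds, below all random lists. Of 25 Wnt targets, 11 were lower and 2 higher, with a median of -0.76 (percentile 0.04) that became 1.02 under the stroma scaling. Dkk1 was 30.1-fold lower (11.5 to 112), Ccnd1, a cyclin of cell cycle entry, 16.9-fold lower (12.4 to 23.7), and Sfrp2, a secreted Wnt binder, 5.45-fold lower (4.95 to 6.02). Tcf7 was 19.05-fold lower (11.91 to 32.45), whereas Rnf43 was 10.7-fold higher (6.01 to 20.8). Of 38 Wnt ligands and receptors, 18 were lower and 7 higher (median -0.88, below all random lists; 0.90 under the stroma scaling). The higher ones included Wnt7b at 30.3-fold (22.4 to 42.01), Wnt6 at 18.3-fold (12.3 to 28.3), and Wnt3, with 0 counts in the control, at least 166-fold against 3 counts. Of 20 beta-catenin partners, 7 were lower and 2 higher (median 0.11, percentile 28.3; -0.24 without the 20 most abundant genes), and Jup was 10.6-fold higher (9.42 to 12.1). Of 18 adherens junction genes, 7 were lower and 7 higher (median -0.20, percentile 14.8; 1.59 under the stroma scaling). Cdh2 and Cdh11, cadherins of mesenchyme, were 43.3-fold (24.1 to 87.3) and 18.4-fold lower (15.1 to 22.6), and Cdh1 was 24.6-fold higher (20.6 to 29.6). The epidermis and hair list, which includes Cdh1, had a median of 5.99 in the same library. Whether the higher counts of Jup, Rnf43, Wnt3, Wnt6, Wnt7b and Cdh1 came from epidermal or mesenchymal cells was therefore not separated.

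Muscle, dermis, meninges, pericyte and endothelial lists had negative medians in the dTF-cKO, and epithelial genes were higher. Of 18 epidermis and hair genes, 18 were at least 2-fold higher (median 5.99, above all random lists). The basal keratins Krt14 and Krt5 were 370-fold (239 to 606) and 188-fold higher (152 to 235), and Krt17, a keratin of early and regenerating epidermis, 317-fold (195 to 555). Of 20 skeletal muscle genes, 20 were lower (median -5.67, or -5.56 with bounds, below all random lists), and Myh3, the embryonic myosin, had 1719 counts in the control and 1 in the dTF-cKO. The dermis median was -1.16 (percentile 0.02; 0.62 under the stroma scaling). The meninges and smooth muscle and pericyte medians were -2.24 and -2.09, both below all random lists, and -0.46 and -0.31 under the stroma scaling. Pdgfrb, a receptor of pericytes, was 15.7-fold lower (11.5 to 22.1), while the contractile gene Tagln was 6.96-fold higher (5.94 to 8.18). Of 17 endothelial genes, 9 were lower and 0 higher; their median was -1.02, which became 0.77 under the stroma scaling. Kdr, the main VEGF receptor, was 12.4-fold lower (7.87 to 20.5). Of 8 erythroid genes, 4 were higher and 0 lower (median 1.09, percentile 98.0). The embryonic globins Hbb-y and Hba-x were 35.2-fold (21.4 to 62.1) and 24.7-fold higher (16.6 to 38.1), against 3.40-fold for the adult globin Hbb-bs (3.31 to 3.49). Ribosomal protein genes took 7.87% of counts, against 3.27% in the control, and transcripts of the mitochondrial genome 0.529%, against 0.790%. The immediate early and heat shock list, which follows tissue handling as well as stress, had a median of 2.38.

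In all, 2363 genes were at least 2-fold higher and 2530 at least 2-fold lower in the dTF-cKO, and the counting interval excluded 1 for 4869 of these. The simulated libraries gave 1474 and 1446.5 with the assumed dispersion, and 13.6 and 18.8 with counting error alone. The balance rested on the scaling: without the 20 most abundant genes it was 1602 higher and 3395 lower, and under the stroma scaling, which raises every gene and list median of this comparison by 1.78 and moved the median of all genes from 0.06 to 1.84, it was 9082 higher and 574 lower.

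The Cre-carrying libraries were compared directly to ask how the fx/dm genotype differs from fx/fx under the same Cre; the Ctnnb1 transcript was lower in the dTF-cKO (442 CPM) than in the cKO (745 CPM). Osteoblast and cartilage genes were lower in the dTF-cKO than in the cKO, with medians of -2.53 and -2.11 that were -0.65 and -0.23 under the stroma scaling. Of 25 osteoblast genes, 17 were at least 2-fold lower and 1, Atf4, was 2.88-fold higher (2.59 to 3.22). The osteoblast median was -2.41 with bounds, below all random lists. Ibsp was 175-fold lower (74.8 to 541) and Alpl 26.8-fold lower (16.1 to 48.3). Of 22 chondrocyte genes, 19 were lower and 0 higher, with a median below all random lists. Acan was 69.5-fold lower (38.6 to 139.8) and Matn1 22.2-fold lower (14.2 to 36.7). Osteoprogenitor genes had 14 of 21 lower (median -1.45, below all random lists; 0.43 under the stroma scaling), and hypertrophic genes 7 of 9 lower and Vegfa 4.71-fold higher, with a median of -2.41. Of 25 Wnt targets, 13 were lower and Rnf43, chosen after its value was seen, was 2.16-fold higher (1.53 to 3.07); their median of -1.14, below all random lists, became 0.74 under the stroma scaling. Ccnd1 was 9.39-fold lower (6.80 to 13.3) and Apcdd1 5.19-fold lower (4.01 to 6.80). Wnt ligands and receptors had 19 lower and 5 higher (median -0.89, percentile 0.02; 0.99 under the stroma scaling), with Wnt3 at 8.36-fold higher (6.17 to 11.6). Beta-catenin partners had 5 lower and 0 higher (median 0.06, percentile 27.6; -0.07 with libraries scaled to their totals). Adherens junction genes had 7 lower and 4 higher (median 0.32, percentile 77.3; 0.037 without the 20 most abundant genes and 2.20 under the stroma scaling).

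Genes of the epidermis list went both ways. The median was 0.10 (percentile 26.8; -0.03 with libraries scaled to their totals), with 4 genes at least 2-fold lower and 4 higher in the dTF-cKO. Among the lower ones, Krt1 was 161-fold lower (133 to 198), Lor 107-fold (83.8 to 138), Krt10 21.6-fold (20.2 to 23.1) and Ivl 12.5-fold. The higher ones were Krt17 at 38.9-fold (32.0 to 47.8), the epithelial adhesion gene Epcam at 10.8-fold (7.97 to 14.8), and Cdh1 at 4.33-fold and Krt5 at 2.22-fold, both chosen after their values were seen. Sprr2d, a gene of the cornified envelope, was at least 21.9-fold higher. Krt8 and Krt75, keratins of simple epithelia and of hair follicles, were 36.2-fold (30.1 to 43.9) and 130-fold higher (55.4 to 401). Skeletal muscle genes were lower in 20 of 20 (median -3.24, or -3.13 with bounds). Endothelial genes were lower in 13 of 17 (median -1.78; 0.10 under the stroma scaling), among them Kdr at 19.01-fold (12.1 to 31.5). Erythroid genes were higher in 6 of 8 (median 1.55, percentile 99.99), with Hbb-y at 27.8-fold (17.0 to 49.1). Across all genes, 1759 were at least 2-fold higher and 2490 lower, 4210 of them with an interval excluding 1. The simulated libraries gave 1472 and 1463 with the assumed dispersion, and 23.7 and 22.3 with counting error alone. Without the 20 most abundant genes the observed counts were 1122 and 3276. Under the stroma scaling, which raises every gene and list median here by 1.88, they were 9321 and 466.

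Hedgehog, BMP, FGF and TGF-beta lists had negative medians in the dTF-cKO under TMM scaling, and under the stroma scaling all but hedgehog turned positive. Hedgehog genes were lower in 11 of 12 in the dTF-cKO (median -2.01, below all random lists), and in 10 of 12 against the cKO (median -1.94, or -1.51 with bounds), but under the stroma scaling these medians were close to 0, at -0.23 and -0.06. The hedgehog targets Gli1 and Hhip and the receptor Ptch1 were 16.2-fold (9.51 to 30.0), 13.8-fold (6.48 to 34.9) and 4.53-fold lower than in the control (3.52 to 5.88). In the cKO, 1 of the 12 was at least 2-fold higher and 3 were lower, Ihh, Hhip and Gli1 (median -0.27, percentile 2.13). Notch genes were higher in the cKO for Nrarp, Dll1 and Jag2, at 4.36-fold, 4.45-fold and 2.56-fold, and lower for 0 of 15 (median 0.74, percentile 99.97), in the library in which 17 of 18 epidermis and hair genes were higher too. In the dTF-cKO, 4 were higher and 6 lower, with a median of 0.30 (percentile 73.0) that was -0.05 without the 20 most abundant genes. Jag2 was 8.99-fold higher (7.14 to 11.4) and Heyl, a Notch target of pericytes, 107-fold lower (18.9 to 4267). Against the cKO 2 were higher and 7 lower (median -0.77, percentile 1.17; 1.11 under the stroma scaling). BMP signalling genes had 3 higher and Smad9 lower in the cKO, with a median of 0.15 (percentile 77.7) that was -0.18 under the stroma scaling, and Fst, an activin and BMP antagonist, was 4.78-fold higher (2.99 to 7.94). In the dTF-cKO 11 of 24 were lower and Fst, chosen after its value was seen, was 5.11-fold higher (median -0.56, percentile 2.77; 1.22 under the stroma scaling). Against the cKO 11 were lower and 0 higher (median -0.80, percentile 0.48; 1.09 under the stroma scaling). FGF genes had 10 of 20 lower in the dTF-cKO (median -1.02, percentile 0.22) and 10 lower and 2 higher against the cKO (median -1.12, percentile 0.10), and both medians became 0.76 under the stroma scaling. In the cKO the FGF median was -0.09 (percentile 14.5), or 0.01 with libraries scaled to their totals, with Fgf7 at 2.40-fold higher (1.34 to 4.42) and Fgf18, a ligand of calvarial bone growth, at 2.62-fold lower (1.38 to 5.30). TGF-beta genes had 1 of 18 lower in the cKO, Tgfb1, chosen after its value was seen (median -0.17, percentile 3.48). In the dTF-cKO 7 were lower and Cyr61, a matricellular gene, was 15.6-fold higher (median -0.71, percentile 0.06; 1.07 under the stroma scaling). Against the cKO 5 were lower and Cyr61 was higher (median -0.29, percentile 1.07; 1.59 under the stroma scaling).

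Dermis and skin fibroblast genes had 3 of 17 higher and 1 lower in the cKO, with a median of 0.17 (percentile 79.5) that was -0.16 under the stroma scaling. Against the cKO, 12 were lower in the dTF-cKO and Crabp1, chosen after its value was seen, was 2.34-fold higher (median -1.32; 0.56 under the stroma scaling). Dpt, a dermal matrix gene, was 2.81-fold higher in the cKO (2.15 to 3.70), and Lum, a collagen-binding proteoglycan, 4.08-fold lower in the dTF-cKO (3.65 to 4.57). Meninges genes had 1 of 13 higher and 1 lower in the cKO, Ptgds and Crym (median 0.17, percentile 76.8; -0.16 under the stroma scaling), and 11 lower in the dTF-cKO against the cKO (median -2.48). Smooth muscle and pericyte genes had a median of 0.38 in the cKO (percentile 97.0) and -2.62 in the dTF-cKO against the cKO. Tendon genes had 2 of 6 lower and 1 higher in the cKO (median -0.62, percentile 0.42), and 4 lower and 1 higher in the dTF-cKO (median -1.97, percentile 0.10; -0.19 under the stroma scaling), with Mkx, a tendon transcription factor, at 2.42-fold (1.64 to 3.63) and 8.61-fold lower (4.51 to 18.5). Against the cKO 3 were lower (median -0.74, percentile 6.35; 1.14 under the stroma scaling). Adipocyte genes had 2 of 9 higher and 1 lower in the cKO (median 0.51, percentile 97.9). They had 3 higher and 4 lower in the dTF-cKO (median -0.28, percentile 24.5; 1.499 under the stroma scaling), and 5 lower against the cKO (median -1.24, percentile 0.46; 0.64 under the stroma scaling). Cebpa, a factor of fat and epidermal differentiation, was 13.1-fold higher in the cKO (8.79 to 20.2) and 5.49-fold higher in the dTF-cKO (3.59 to 8.68).

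The differences of the Cre-carrying libraries from the control were then set side by side. Both were at least 2-fold higher for 832 genes and lower for 434, against 228 and 171 from the products of the separate counts over 12127. They pointed opposite ways for 72 genes higher in the cKO and lower in the dTF-cKO (product 245), and for 21 the reverse (product 160); simulated libraries with added dispersion and no genotype effect gave 18.8 and 19.9. Among chondrocyte genes, 15 of 22 were higher in the cKO at any size, 19 were lower in the dTF-cKO, and 12 were both. Pearson's r across genes was 0.609 and Spearman's rho 0.529; genes are not independent replicates, and 1 control library enters both differences. Simulated libraries with no genotype effect gave an r of 0.439 with counting error alone and 0.494 with added dispersion, and the latter gave 621 genes higher in both and 405 lower in both. The single control could not be split, so its part in the shared excess was not measured.

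**Figure D3:**
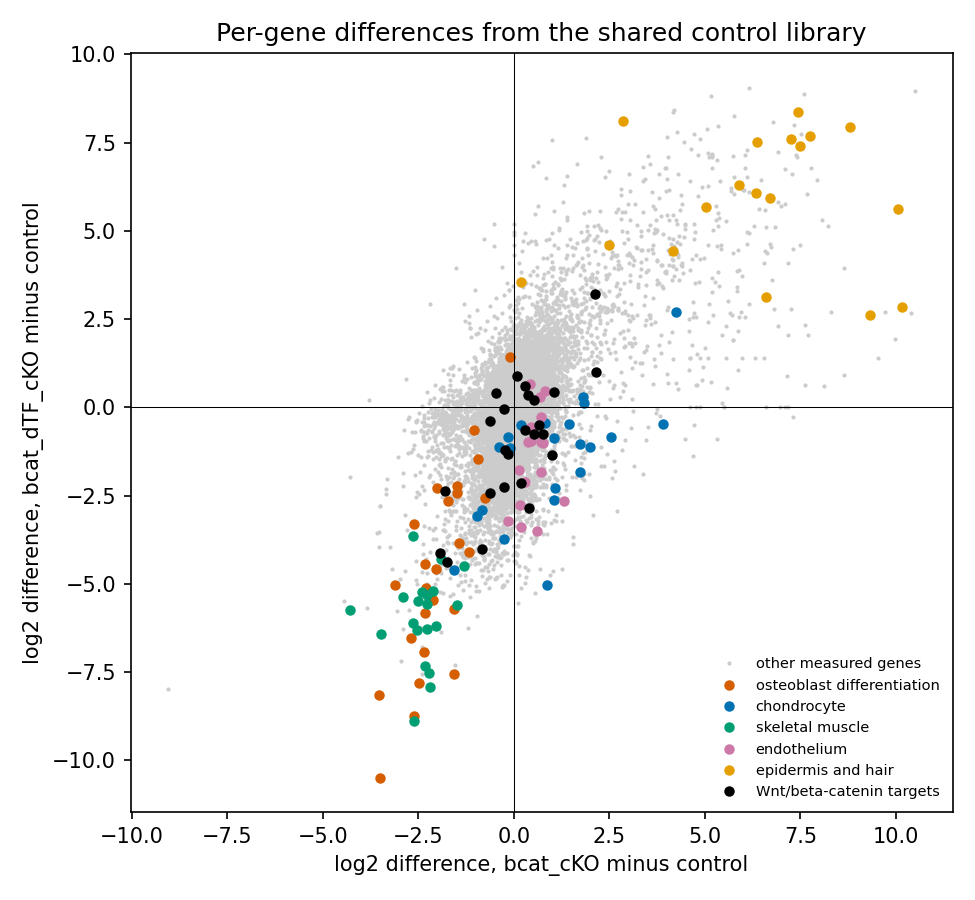
Log2 difference from the control (points), the cKO on the x axis and the dTF-cKO on the y axis, with 6 gene lists in colour. Points are the 12127 measured genes, less those whose symbols had been turned into dates. Both axes share the control library. The medians of the osteoblast and muscle lists lie below 0 on both axes and that of the epidermis list above 0 on both, and 12 of 22 chondrocyte genes lie to the right and below 0.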

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

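The tests of explanations in this part were chosen after the results were seen. The chondrocyte list lay on opposite sides of the control, with medians of 1.06 in the cKO and -1.08 in the dTF-cKO, and this difference was not tested, since each genotype had 1 library. Under the stroma scaling both medians were positive, 0.73 and 0.70. Y-linked genes, which the comparisons are not about, had 362 counts in the cKO and 444 in the dTF-cKO, above the 0 counts of the control. Yam1 and Lars2, looked up after their values were seen, also set the libraries apart: Yam1 took 2.73%, 7.32% and 1.06% of counts in the control, cKO and dTF-cKO, and Lars2 0.186%, 0.746% and 0.0932%.

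In the cKO, osteoblast genes were lower (median -2.04) and cartilage genes higher (median 1.06). The gap between these lists was 3.11 (95% bootstrap interval over genes 1.97 to 3.92) under any scaling of the libraries. Skin holds neither tissue, so the gap argues against dilution by skin alone only as far as skin lowers both lists alike. That premise was not checked, and Trps1 stands in both the chondrocyte and the dermis lists. For the osteoblast genes by themselves dilution stays open: their median lay -2.37 from that of the stroma lists (-2.75 to -1.76), but skin would bring stroma genes with it, so this excludes nothing. A smaller share of bone with its neighbouring muscle in the dissected piece may have contributed: the skeletal muscle list, which shares no gene with the osteoblast list, had a median of -2.31 with an upper quartile of -2.18. An action of the genotype on the mesenchyme cannot be told apart from a difference in dissection or between embryos with 1 library per genotype, and the difference in sex-linked transcripts stays open as well.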

How the results depend on the processing

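All alternatives were fixed in advance except the stroma scaling, which was chosen after seeing the data. The log2 difference of Ctnnb1 in the cKO stayed negative, from -0.79 to -0.36. That of the dTF-cKO ran from -1.58 to -1.19, and that between the Cre-carrying libraries from -1.05 to -0.69, except under the stroma scaling, where they became 0.57 and 1.13. Osteoblast medians stayed negative under all alternatives run for them, at -2.37 to -1.81, -5.03 to -2.80 and -2.83 to -0.65. Chondrocyte medians kept their sign in the cKO (0.73 to 1.16) and between the Cre-carrying libraries (-2.40 to -0.23). Under the stroma scaling the chondrocyte median of the dTF-cKO became 0.70, and the Wnt target median became -0.13 in the cKO, 1.02 in the dTF-cKO and 0.74 between them. The Wnt target median of the cKO was -0.036 at a floor 4 times as high. Genes at least 2-fold lower in the cKO numbered 1347 under the stroma scaling. The higher and lower counts became 9082 and 574 for the dTF-cKO, and 9321 and 466 between the Cre-carrying libraries. Without the 20 most abundant genes, 1122 were higher between these. With no floor the counts were 2149 higher and 2293 lower in the cKO, 4619 lower in the dTF-cKO, and 3073 and 4536 between them. At 4 times the floor they were 675 and 325, 1228 lower, and 1169 lower. A 1.5-fold rule gave 2195 and 1602 in the cKO, 3791 higher in the dTF-cKO and 3237 higher between them. A 3-fold rule gave 692 and 382, 1255 and 1586, and 710 and 1516. The number of genes measured or the size rule itself accounts for these last counts by construction. The stroma scaling centres each comparison separately and moves every gene in it by the same amount, -0.33, 1.78 and 1.88 in the 3 comparisons. These shifts do not add up as library factors would, and reversals under it follow by construction. For the totals without the 20 most abundant genes and the Wnt target median at the higher floor, the cause was not tested. The correlation was 0.565 with no floor and 0.657 at 4 times the floor. The median of all genes was 0.06, 0.06 and 0.01 in the 3 comparisons, 0.16, 0.03 and -0.12 with totals, -0.01, -0.29 and -0.29 without the 20 most abundant genes, and -0.27, 1.84 and 1.89 under the stroma scaling. Of 35 list medians, totals changed the sign of 2, 0 and 2, and the stroma scaling of 9, 14 and 17. No paired analysis was possible because each genotype had 1 library, and no count could be rerun without a doubted library. At this depth a count of 0 allows up to 1.07 CPM.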

Other observations

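The tests of explanations in this part were chosen after the results were seen, except that for yolk sac or placental tissue; the gene lists were planned. Genes of stress and growth also set the dTF-cKO apart. Of 13 p53 and apoptosis genes, 12 were at least 2-fold higher than in the control (median 2.35) and 10 were higher than in the cKO (median 2.14), both above all random lists. Pmaip1, a trigger of apoptosis, was higher by a ratio of 90.4 (54.5 to 162), and Cdkn1a, an inhibitor of the cell cycle, by 8.99 (8.02 to 10.1). In the cKO 3 were higher and Bbc3 lower, with a median of 0.09 (percentile 57.3) that was -0.24 under the stroma scaling. Of 22 immediate early and heat shock genes, 18 were higher in the dTF-cKO (median 2.38), 16 were higher than in the cKO with Fosb, chosen after its value was seen, lower (median 1.68), and 7 were higher in the cKO with Nr4a2, chosen in the same way, lower (median 0.49, percentile 99.96). The heat shock gene Hspa1a had 11, 119 and 1447 counts in the control, cKO and dTF-cKO. Of 20 hypoxia and glycolysis genes, 16, 13 and 6 were higher in the dTF-cKO against the control, against the cKO and in the cKO (medians 1.93, 1.29 and 0.62). Slc2a1, the main glucose transporter of many tissues, had 285, 887 and 6660 counts. Of 56 ribosomal protein genes, 50 were higher in the dTF-cKO (median 1.32), 25 were higher than in the cKO (median 0.99), and 2 were higher in the cKO (median 0.31; -0.02 under the stroma scaling). The 13 genes of the mitochondrial genome had 11 lower in the dTF-cKO (median -1.46; 0.32 under the stroma scaling), 7 lower than in the cKO (median -1.16; 0.72), and 4 lower in the cKO despite a median of 0.22, which was -0.11 under the stroma scaling. Of 30 cell cycle genes, 9 were lower in the dTF-cKO (median -0.42; 1.36 under the stroma scaling), 6 were lower than in the cKO (median -0.40; 1.49), and 0 differed 2-fold in the cKO, with a median of 0.01 that was 0.11 with totals, -0.02 with median-of-ratios factors and -0.32 under the stroma scaling. Tk1, a gene of DNA precursor synthesis, was lower by a factor of 6.58 in the dTF-cKO (3.84 to 12.1).

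Among the remaining cell types, osteoclast genes had 6 of 7 lower in the dTF-cKO (median -2.27, percentile 0.04; -0.49 under the stroma scaling), and 4 lower and 1 higher against the cKO (median -1.16; 0.72 under the stroma scaling). Nfatc1, a factor of osteoclast formation, was lower by a factor of 26.1 than in the control (14.8 to 50.9). Macrophage and leukocyte genes had 6 of 16 lower and 2 higher in the dTF-cKO (median -0.25; 1.53 under the stroma scaling), and 9 lower against the cKO (median -1.07; 0.81). Neuron and glia genes had 6 of 11 lower in the dTF-cKO (median -1.13; 0.65 under the stroma scaling) and 5 lower against the cKO (median -0.83; 1.05). Melanocyte genes had 3 of 5 higher and Mitf lower in the dTF-cKO (median 1.83), and 4 lower against the cKO (median -1.48; 0.40 under the stroma scaling). Among Hox genes, Hoxd8 had 7, 73 and 12 counts in the control, cKO and dTF-cKO, and Hoxc13, a gene of hair and nail, 1, 13 and 34. The 5 sex-linked genes had medians of 5.28, 5.71 and 0.55 (4.88 and 5.32 with bounds against the control). Against the control these medians reflect the 4 Y-linked genes, which had 0 counts there, while Xist was lower in both Cre-carrying libraries. Reference genes were not level: of 15, 3 were higher in the cKO (median 0.34), 7 were higher and Gusb lower in the dTF-cKO (median 0.83), and 5 were higher and 2 lower between them (median 0.67), with Gapdh higher by a ratio of 3.81 in the dTF-cKO (3.63 to 3.99).

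Epidermal genes were higher in both Cre-carrying libraries. Skin carried into the dissected tissue stays open. The lower of the melanocyte medians was 1.83, from a list of which 2 of 7 genes reached the floor in the control. However, the dermis list did not follow in the dTF-cKO (median -1.16), and the stroma scaling, built in part on the dermis list, cannot tell whether it did. The abundant epidermal genes Krt10 and Krt5 had 21, 19639 and 901 counts and 86, 5759 and 12663 counts in the control, cKO and dTF-cKO; 9 of the 18 genes were above the floor in the control and 2 stood in another list. Carried skin and an action of the genotype cannot be told apart with 1 library per genotype, and the labels name no sorting step that would have removed epidermis.

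Embryonic globins were higher in the dTF-cKO, and more blood alone was argued against: they made 2.15% of its globin counts (2.02% to 2.29%), against 0.182% in the control (0.131% to 0.245%) and 0.421% in the cKO (0.324% to 0.537%). Yolk sac or placental tissue was argued against too, since 8 of its marker genes summed to 1.07 CPM, against 0.559 CPM in the control. An earlier developmental stage stays open, since the keratins cannot decide it. The log2 ratio of late to basal keratins (Krt1, Krt10 and Lor over Krt5 and Krt14) was -6.41 relative to the cKO and -2.99 relative to the control. Krt1 and Lor were already among the 12 lowest genes against the cKO, so a low ratio there was no independent check. Genes of the cornified layer went both ways: Hrnr had 4270 and 14 counts in the cKO and dTF-cKO, and Sprr2d 0 and 65. Against an earlier stage, the ratio was 2.30 in the cKO and -1.11 in the control, from 49 late counts. It thus ranks the cKO and control in the other order than the embryonic globin share does, and the stated stage is the same for all 3 libraries. The genotype stays open and untested.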
